A study of Mus musculus with 10 samples.

How the data were processed

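The authors deposited 3 processed tables of the same 10 libraries: raw counts per gene symbol, counts per Ensembl gene, and a table of genes with counts, CPM, log2 fold changes against D2, p values and false discovery rates (FDR). The deposited counts per symbol covered 52459 symbols with 31078950 to 33418015 counts per library, and the second table held counts for 55298 Ensembl genes at similar depth. A symbol was found for 98.4% of the Ensembl genes, and 37 mitochondrial genes were present. No column belonged to other samples and every row named a gene. Per the submitters' processing notes, STAR, HISAT2 2.1.0, featureCounts 1.6.3 and limma were used with mm10, but the role of each is not given, nor are the counting options, the use of strand or the gene model. The reference annotation, GENCODE vM21 on mm10, was used only for GC content and transcript length.

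The deposited raw counts were analysed with R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. One quasi-likelihood fit of all 10 libraries with 1 coefficient per group had 5 residual degrees of freedom, used TMM scaling and the default filterByExpr, and kept 18818 genes. The common dispersion was 0.00111, a coefficient of variation of 3.34% between replicates, with 14.3 prior degrees of freedom. P values were adjusted by Benjamini and Hochberg over all tested genes of a comparison, and a gene was called at an adjusted p under 0.05. Groups, comparisons, tests, the 29 gene lists and the alternatives were fixed before the data were examined. Lists were tested by camera with its preset correlation of 0.01, by camera with the correlation estimated from the data, and by fry. Each was adjusted over the 29 lists. Some lists share genes, such as Foxa2 (endoderm and node) and Cldn6 (endoderm and epithelial), so their member counts are not independent.

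Genes were named by 1 rule: per comparison the 10 largest rises and 10 largest falls among called genes with groups that did not overlap, at least 5 CPM in a group and no predicted or clone name; up to 4 called members per list with the largest change; Hox genes in D7G against D7; and Gdf11, T, Sox2, Pou5f1, Tbx6, Sox1 and Cdx2 throughout. From these, genes whose fold change or call did not hinge on a library were preferred, a choice made after the data were seen. Where a group had 0 counts the fold is given as a bound, with a floor of 3 counts over the group, and with 1 to 3 counts as a ratio with its 95% interval. Intervals and floors cover counting error only, as the notes mention no molecular identifiers that would separate PCR copies. The relation of fold change to paralogue group was tested over the 39 Hox genes with 100000 permutations.

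The alternatives were DESeq2, limma-voom, other scaling factors, no filter and a filter of at least 1 CPM in 2 libraries, the second table, only the libraries of the groups compared, a term for the replicate number, and each library left out in turn. A group then has 1 library and is assumed to vary like the others, so calls lost or gained in these fits rest on the spread of other groups. The list tests with an estimated correlation were among them. Added after the data were seen were the counts of at least 2-fold under each alternative, the member counts of lists without each library, the Hox relations with genes of 0 counts in a group at their bound or left out, and a pair of further Hox relations.

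Recall for D7G against D7 was measured with edgeR in simulated counts with the depth of the libraries and gene dispersions estimated over all 10 of them. In these, 50 genes per fold size were changed. Recall was 36% at 1.2-fold, 58% at 1.5-fold, 78% at 2-fold and 94% at 4-fold, and 5 of 138 calls fell on unchanged genes. Only 200 genes were changed, against 7661 called in the data. D7G replicates also differed the most (mean chi-square per gene 4.40, against 1.99 in D2 and 2.96 in D7). Recall and false calls in the real comparison can therefore differ. The median SE of a log2 fold change was 0.087 to 0.090. Depth of this size leaves genes under about 1 CPM, such as Hoxc12 before D7G, with few counts and wide intervals, so a missing call there is not evidence of no change. TMM scaling assumes that most genes do not change, while 6782 to 12367 genes were called per comparison, so small shifts shared by many genes depend on it. Overlapping genes such as Hoxd3 and Hoxd4 have separate counts, but how reads in an overlap were assigned is not stated. Reads from antisense or read-through transcripts in the Hox clusters could be counted for a neighbour. RNA of all cells in a dish was pooled, so a change in the share of a cell type and a change within cells look the same.

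The authors' deposited table listed 14983 genes with FDR up to 0.100 and its counts equalled the raw table for 100% of entries. Its difference of log2 fold changes between D7G and D7 correlated at 0.999 with the values here, and 7352 of the 7661 genes called in that comparison were listed. That table tests all groups against D2, so its p values answer another question. The authors' CPM were not used here.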

Results

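RNA was sequenced from C57BL/6 mouse embryonic stem cells (ESCs) that were carried towards neuromesodermal progenitors (NMPs), cells of the posterior embryo that supply both spinal cord and trunk mesoderm. The medium was supplemented with basic Fgf (10 ng/ml) on day 0 and with CHIR99021 (5 µM), a Gsk3 inhibitor that activates Wnt signalling, on day 2, and the cells were split on day 3. Some cells received Gdf11 (50 ng/ml), a secreted ligand of the Tgf-β family, on day 6 for 24 h. The 5 groups were day 2 (D2, labelled epiblast stem cells), day 3 (D3), day 6 (D6), day 7 (D7) and day 7 with Gdf11 (D7G), with n = 2 libraries each. The labels do not say whether replicates were separate cultures, so p values measure only the spread between these libraries, which may be technical. Libraries held 31078950 to 33418015 gene counts, and 18818 genes were tested. Where a library is left out, its group keeps 1, and the spread used for it comes from the other groups. Log2 fold changes are given ± SE, and expression in CPM as group means ± SD of 2 libraries. The SE was derived from the fold change and the F statistic of the fit of all 10 libraries. Its spread per gene is pooled over the 5 groups and drawn towards that of other genes. It can therefore understate the spread of D7G, whose replicates differed the most (mean chi-square per gene 4.40).

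Replicates correlated at 0.995 or more across genes and libraries of different groups at 0.990 or less. Replicates still differed by more than counting noise, with a mean chi-square per gene of 1.99 to 4.40. The first 3 principal components held 64.9, 13.8 and 11.6% of the variance, and the replicates of every group lay next to each other. Mitochondrial genes took 1.86 to 2.48% of the counts.

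**Figure D1:**
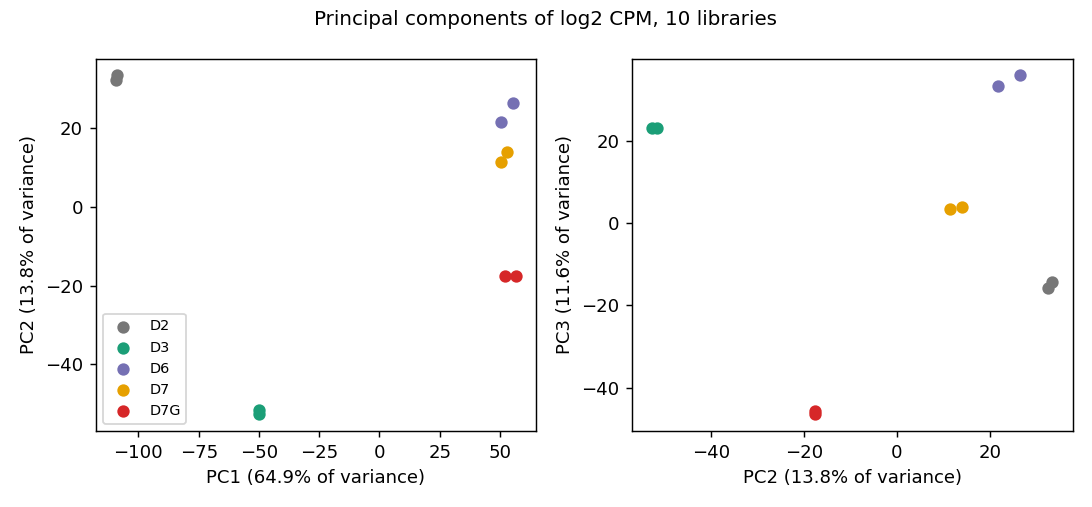
Principal components of the 10 libraries, with the share of the variance each component held on its axis.

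The comparison of D3 with D2 asked what changed in the day after CHIR99021 was added. All 15 genes of the caudal epiblast and NMP list rose, with a median log2 fold change of 4.87. T (Brachyury), the T-box factor of the primitive streak and tail bud, went from 0.919 ± 0.0892 to 232 ± 1.33 CPM (7.97 ± 0.08, adjusted p = 4.24e-23). Cdx2, a homeobox factor of the posterior embryo, went from 0.591 ± 0.00238 to 154 ± 0.381 (8.02 ± 0.09). All 12 primed epiblast genes fell (median -2.09): Fgf5, a growth factor of the postimplantation epiblast, from 19.9 ± 0.289 to 0.354 ± 0.0669 CPM (-5.80 ± 0.19). Otx2, a homeobox factor of the anterior embryo, fell from 36.1 ± 0.772 to 0.876 ± 0.0611 CPM (-5.36 ± 0.15). Pou5f1 (Oct4), a core pluripotency factor, fell from 565 ± 4.2 to 255 ± 6.2 CPM (-1.15 ± 0.06). Sox2, a factor of both pluripotent and neural cells, stood at 163 ± 5.45 and 172 ± 8.27 CPM (0.08 ± 0.04, adjusted p = 0.148, or 0.13 with adjusted p = 0.0416 without D3 replicate 2).

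Among other NMP genes, Sp5, a Wnt-induced transcription factor, rose by 8.59 ± 0.17 and Cdx1 by 7.93 ± 0.12. Wnt3a, a ligand of the primitive streak, rose by 7.58 ± 0.23 and Nkx1-2, a homeobox gene of the NMP region, by 6.09 ± 0.08. Evx1, an even-skipped homeobox gene of the posterior streak, had 1 to 3 counts on D2, and its ratio was 645 (95% interval 178 to 5335). Evx1os, which overlaps it in antisense, had a ratio of 421 (116 to 3484), and Hoxb5os, in the Hoxb cluster, 283 (78.0 to 2343). Strand use in counting is not stated, so these and their neighbours are uncertain. Msgn1, a factor of presomitic mesoderm, had 0 counts on D2 and 6.61 ± 0.683 CPM on D3, at least 134-fold. Among the largest falls were also Enpp2 (-5.34 ± 0.10), the kinase gene Pim2 (-4.54 ± 0.06), Pou3f1 (-3.93 ± 0.10), Ntrk2 (-3.99 ± 0.15) and Bcl11a (-3.80 ± 0.17). Gdf11 itself rose from 7.14 ± 0.656 to 22.6 ± 0.415 CPM (1.66 ± 0.09).

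Of the Hox genes, which set position along the body axis, all 12 in paralogue groups 1 to 4 rose (median 3.84). So did 14 of 15 in groups 5 to 9 (4.59) and 9 of 12 in groups 10 to 13 (2.16, or 2.08 with low-count genes at their bounds). Hoxb1 rose by 4.46 ± 0.14, Hoxb4 by 3.97 ± 0.15, Hoxc8 by 6.35 ± 0.19 and Hoxb9 by 5.65 ± 0.13, whereas Hoxa6 (0.63 ± 0.66) did not pass. In groups 10 to 13 the levels stayed low, Hoxc13 reaching 4.56 ± 0.652 CPM (2.44 ± 0.22), and only 5 rose without D2 replicate 1 and 4, with 1 fall, without D3 replicate 1. Camera gave adjusted p = 1.98e-08, 1.19e-08 and 0.00974 for the 3 lists, and adjusted p = 0.112, 0.0957 and 0.195 with an estimated correlation. In the presomitic and somitic list 9 rose, 2 fell and 4 did not pass (adjusted p = 0.0191, adjusted p = 0.136 with an estimated correlation). Rspo3 (5.82 ± 0.18) and Tbx6, a T-box factor of paraxial mesoderm (1.77 ± 0.75 to 4.94 ± 0.48 CPM, 1.47 ± 0.23), were among the rises and Tcf15 (-2.32 ± 0.12) among the falls.

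Of 12 Wnt targets 11 rose (adjusted p = 3.87e-06, adjusted p = 0.0957 with an estimated correlation), such as Notum (3.59 ± 0.12) and Axin2 (3.44 ± 0.08), both feedback inhibitors, while Ccnd1 (-0.01 ± 0.04) did not pass. Of 9 retinoic acid response genes 8 rose (adjusted p = 1.05e-04, adjusted p = 0.0692 with an estimated correlation), among them Stra6 (3.22 ± 0.08) and Crabp1 (2.64 ± 0.07). The protocol names B27 supplement with or without vitamin A, a precursor of retinoic acid, and does not say which these libraries had, so values of this list can depend on the medium. Of 8 Bmp targets 5 rose and 1 fell, or 0 fell without D2 replicate 2 or either D3 library, and Msx1 rose by 4.78 ± 0.16. This list had adjusted p = 0.0306, adjusted p = 0.195 with an estimated correlation, and 0.0848 with only the libraries of both groups in the fit. Of 14 Tgf-β, Activin and Nodal targets 2 rose and 8 fell, or 1 rose without D2 replicate 2, with Ctgf at -1.08 ± 0.07 and Nodal at -0.89 ± 0.07. This list had adjusted p = 0.0191, adjusted p = 0.179 with an estimated correlation. The naive pluripotency list had 9 rises and 1 fall (Tfcp2l1 1.98 ± 0.08, Fgf4 -1.24 ± 0.07), and the endoderm list 6 rises (Sox17 2.52 ± 0.15). The mesenchymal list had 8 rises (Cdh2 1.59 ± 0.06) and the embryo-fibroblast list 8 (Postn 1.59 ± 0.10, Col1a1 0.88 ± 0.08). The 4 adjusted p values were 0.00576, 0.0072, 0.00367 and 0.0175, and adjusted p = 0.464, 0.371, 0.211 and 0.25 with an estimated correlation.

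All 10 mitosis genes fell (Top2a -0.81 ± 0.03, Plk1 -0.80 ± 0.04), as did 9 of 10 DNA replication genes (Mcm2 -0.46 ± 0.03). Falls were also found in 8 of 10 hypoxia and glycolysis genes (Bnip3 -1.17 ± 0.07, Ldha -0.96 ± 0.04) and 9 of 10 cholesterol synthesis genes (Insig1 -0.59 ± 0.04). Of the p53 targets, 10 of 12 rose (Fas 2.37 ± 0.21, Cdkn1a 1.64 ± 0.05). Camera gave adjusted p = 1.52e-05, 0.00576, 2.59e-04, 0.00259 and 0.00601, and adjusted p = 0.136, 0.195, 0.0957, 0.112 and 0.136 with an estimated correlation. The DNA replication median was -0.22, or -0.14 with scaling by library totals. Sox1, an early neural factor, fell from 75.6 ± 0.787 to 27.3 ± 0.11 CPM (-1.47 ± 0.06). The spinal cord list had 8 rises and 5 falls, or 5 and 4 without D2 replicate 2 (adjusted p = 0.533). The 9 other lists had no call: neurons (adjusted p = 0.668), forebrain and midbrain (0.391), neural crest (0.262), node and notochord (0.164, 0.0184 without a filter), and lateral plate (0.457). Also without a call were Fgf-Erk targets (adjusted p = 0.467), Lin28 and let-7 (0.983), epithelial (0.983) and immediate early genes (0.521).

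Of all tested genes 5567 were higher and 5440 lower on D3, 1632 and 1036 of them by at least 2-fold. Camera called 19 of 29 lists, 13 up and 6 down, of which 2 held with an estimated correlation between genes. These were the NMP list (adjusted p = 8.35e-13, 0.0329 with an estimated correlation) and the primed epiblast list (1.62e-08 and 0.0329). For each set fry's PValue tests whether its genes move, on balance, one way and PValue.Mixed whether they change in either direction. Neither compares the set with other genes. Their adjusted p passed for 25 and 29 lists, and for the neuron, Lin28 and epithelial lists the median, mean and camera direction differed in sign. Member counts adjusted over each list alone matched those over all genes except in the Tgf-β list (3 higher, 9 lower).

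The comparison of D6 with D3 asked what changed over the next 3 days of the course. Meox1, a homeobox gene of the somites, went from 0.277 ± 0.0448 to 43.1 ± 7.73 CPM (7.26 ± 0.20, adjusted p = 7.98e-17), and Hoxc10, a posterior Hox gene, from 0.861 ± 0.0394 to 45.3 ± 2.43 (5.71 ± 0.12). T fell from 232 ± 1.33 to 41.7 ± 2.28 CPM (-2.47 ± 0.05) and Wnt3a from 19.7 ± 0.376 to 0.597 ± 0.206 (-5.03 ± 0.17). In all, 14 of 15 NMP genes fell while Wnt5a rose (0.39 ± 0.08). All 15 Hox genes of groups 5 to 9 rose, and all 10 epithelial genes fell. Cdx2 went from 154 ± 0.381 to 111 ± 2.79 CPM (-0.47 ± 0.04), Gdf11 from 22.6 ± 0.415 to 56.3 ± 3.57 (1.32 ± 0.06) and Pou5f1 to 147 ± 20.2 (-0.80 ± 0.07).

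Other large rises were Sparcl1, a secreted glycoprotein gene (6.50 ± 0.09), Lrrn3 (6.40 ± 0.22) and Foxc2, a forkhead factor of paraxial mesoderm (5.76 ± 0.30, or 6.62 without D3 replicate 2). The immediate early gene Fosb (2.75 ± 1.05 to 146 ± 3.37 CPM, 5.72 ± 0.12), the ligand gene Bmp5 (5.05 ± 0.26) and Dmrt2, of the dermomyotome (5.05 ± 0.18), also rose. Large falls were Lox, a collagen cross-linking enzyme (-6.01 ± 0.20, or -6.76 without D6 replicate 1) and the intermediate filament gene Prph (59.6 ± 4.93 to 0.935 ± 0.002 CPM, -5.99 ± 0.12). Ltb (-5.16 ± 0.31), Mixl1, a homeobox gene of the primitive streak (-5.11 ± 0.22), and Col1a2 (108 ± 1.62 to 5.38 ± 0.034 CPM, -4.32 ± 0.10) also fell. Msgn1 fell (-4.75 ± 0.28), with -4.08 without D6 replicate 1 and -6.04 without D6 replicate 2. Tbx6 stood at 4.94 ± 0.48 and 3.24 ± 0.107 CPM (-0.61 ± 0.21, adjusted p = 0.0153). This call was lost without D3 replicate 2 (adjusted p = 0.117) or D6 replicate 2 (0.0652), by DESeq2 (0.0795) and in the second table (0.0930).

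Of Hox groups 1 to 4, 10 rose (Hoxd3 3.48 ± 0.19, Hoxc4 2.67 ± 0.07) and 2 fell, or 1 fell without D3 replicate 2 or D6 replicate 2. In groups 5 to 9 Hoxa9 rose by 2.28 ± 0.07 and Hoxc9 by 2.95 ± 0.14. In groups 10 to 13 also 10 rose (Hoxa10 2.86 ± 0.10) and 2 fell (Hoxc13 -1.35 ± 0.19), or 1 without D3 replicate 1 or D6 replicate 1. The median was 3.32, or 2.65 with low-count genes at their bounds. Hoxc12, with 0 counts on D3, rose at least 4.89-fold, and the ratio for Hoxd12 was 45.4 (95% interval 15.2 to 223). The 3 lists had adjusted p = 0.0019, 3.23e-05 and 0.00313, and adjusted p = 0.311, 0.269 and 0.269 with an estimated correlation. The NMP list had adjusted p = 1.69e-04 (median -1.16), and adjusted p = 0.269 with an estimated correlation.

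In the presomitic and somitic list 10 rose, such as Pcdh8 (2.43 ± 0.15) and Tcf15 (1.83 ± 0.12), and 5 fell, such as Rspo3 (-1.94 ± 0.10). These counts were 9 and 2 without D3 replicate 2 and 10 and 3 without D6 replicate 2. Its adjusted p was 0.0403, but 0.0528 without D6 replicate 1, 0.0551 with a filter of at least 1 CPM and 0.0552 with a term for the replicate number, and adjusted p = 0.269 with an estimated correlation. Of 14 spinal cord progenitor genes 10 rose, such as Pax7 (3.44 ± 0.13), Irx3 (3.07 ± 0.08), Pax6 (1.83 ± 0.13) and Sox1 (27.3 ± 0.11 to 55.5 ± 6.08 CPM, 1.02 ± 0.06), and 4 fell, such as Olig2 (-1.67 ± 0.10). The list had adjusted p = 0.0251, adjusted p = 0.361 with an estimated correlation. Sox2 rose to 195 ± 11.7 CPM (0.19 ± 0.04). The epithelial list fell by a median of 1.77 (Cdh1 -1.88 ± 0.07, Esrp1 -2.57 ± 0.08). In contrast, 7 of 9 mesenchymal genes rose and 1 fell (Cdh11 3.03 ± 0.11, Twist1 2.86 ± 0.11, Fn1 -0.87 ± 0.05). Their adjusted p values were 3.31e-05 and 0.00826, and adjusted p = 0.311 and 0.311 with an estimated correlation.

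Of 14 Tgf-β, Activin and Nodal targets 3 rose (Tgfbi 2.34 ± 0.10) and 10 fell (Gadd45b -2.70 ± 0.11, Nodal -1.19 ± 0.08). Camera gave adjusted p = 0.0403, adjusted p = 0.269 with an estimated correlation, 0.0588 with library totals, 0.0505 with a filter of at least 1 CPM and 0.0640 with only the libraries of both groups. Of 8 Bmp targets 6 rose (Id2 3.24 ± 0.09, Msx1 2.13 ± 0.07) and 2 fell, or 0 fell without D3 replicate 2 and 1 without D6 replicate 1. The list had adjusted p = 0.0313, adjusted p = 0.269 with an estimated correlation. Of 12 naive pluripotency genes 11 fell (Klf5 -1.29 ± 0.10, Nanog -0.96 ± 0.08) and Klf4 (0.01 ± 0.07) did not pass. All 10 mitosis genes rose (Top2a 0.51 ± 0.03), as did 8 of 10 DNA replication genes (Pcna 0.44 ± 0.05) and all 10 cholesterol synthesis genes (Hmgcs1 0.99 ± 0.04). Of 12 p53 targets 9 fell (Fas -2.81 ± 0.22, Mdm2 -0.94 ± 0.04) and 3 rose, or 1 without D3 replicate 2 or D6 replicate 1. These 5 lists had adjusted p = 9.51e-04, 9.51e-04, 0.0054, 1.71e-04 and 0.0136, and adjusted p = 0.451, 0.269, 0.269, 0.269 and 0.269 with an estimated correlation.

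Of all genes 6104 were higher and 6263 lower on D6, 1308 and 2662 of them by at least 2-fold. Camera called 15 lists, 10 up and 5 down, and with an estimated correlation 0 passed, 3 at unadjusted p under 0.05, while fry passed 26 by direction and 29 mixed. Without a call were the primed epiblast (adjusted p = 0.404), neuron (0.469), forebrain and midbrain (0.634), neural crest (0.486), endoderm (0.597) and node and notochord (0.486) lists. The same held for the lateral plate (adjusted p = 0.195), embryo-fibroblast (0.397), Wnt target (0.195), Fgf-Erk target (0.41), retinoic acid (0.41), Lin28 and let-7 (0.469) and hypoxia (0.486) lists. The immediate early list had adjusted p = 0.0557, and 0.0358 to 0.0476 without D3 replicate 2, D6 replicate 1 or either D7G library. It was 0.0140 without a filter, 0.0413 with library totals and 0.0489 with upper-quartile factors. The node and hypoxia lists differed in sign between median, mean and test, and member counts over a list alone differed only for hypoxia (6 higher, 4 lower against 6 and 3).

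The comparison of D7 with D6 asked what changed in the untreated cells over the last day. Nkx1-2 fell from 117 ± 4.85 to 39.9 ± 2.54 CPM (-1.55 ± 0.05, adjusted p = 1.02e-13). Cdx2 fell from 111 ± 2.79 to 41.9 ± 1.68 (-1.41 ± 0.05) and T from 41.7 ± 2.28 to 19.8 ± 0.676 (-1.08 ± 0.06). Nhlh1, a factor of newborn neurons, rose from 1.8 ± 0.00387 to 8.98 ± 1.27 CPM (2.31 ± 0.18) and Dcx, a microtubule protein of migrating neurons, by 1.46 ± 0.11. Meox1 fell to 13.7 ± 0.321 CPM (-1.66 ± 0.10) and Tbx6 to 1.07 ± 0.578 (-1.60 ± 0.27, or -2.32 without D7 replicate 2). Sox2 rose to 232 ± 4.04 CPM (0.25 ± 0.04). Gdf11 stood at 52 ± 2.36 (-0.11 ± 0.06, adjusted p = 0.143), but at -0.20 with adjusted p = 0.0448 without D7 replicate 1, and 0.0367 and 0.0369 without D7G replicate 1 or 2.

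Other large rises were the neurotrophin receptor gene Ntrk2 (2.70 ± 0.14), Thbs2 (2.34 ± 0.14), Rgs4 (2.27 ± 0.18) and Robo3, an axon guidance receptor (2.16 ± 0.16). Sema3d (2.15 ± 0.14), the collagen receptor gene Ddr2 (1.98 ± 0.13) and the acetylcholine receptor gene Chrna3 (1.81 ± 0.16) rose as well. Large falls were Lmo2 (19.5 ± 0.163 to 4.59 ± 0.277 CPM, -2.08 ± 0.11), Epha5 (-1.71 ± 0.09), Lrrn3 (-1.45 ± 0.11), Kif26b (-1.40 ± 0.08) and Arg1 (-1.36 ± 0.09). Sox1 stood at 62.6 ± 2.46 CPM (0.17 ± 0.06, adjusted p = 0.0253, but 0.340 without D7 replicate 1). Pou5f1 stood at 128 ± 2.87 (-0.20 ± 0.07, adjusted p = 0.0245, but 0.561 without D6 replicate 2 and 0.0926 without D7 replicate 2).

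Of 15 NMP genes 12 fell and 1 rose (Cyp26a1 0.83 ± 0.10). Of 15 presomitic and somitic genes 10 fell and 2 rose (Pcdh8 0.97 ± 0.10, Lfng 0.90 ± 0.09). Of 14 spinal cord genes 9 rose (Hes5 1.54 ± 0.09, Pax6 0.99 ± 0.09, Pax7 0.90 ± 0.08), or 6 with 1 fall without D7 replicate 2. Of 12 neuron genes 8 rose (Nhlh2 1.61 ± 0.18, Elavl3 1.36 ± 0.11, Tubb3 0.50 ± 0.06), with 1 fall without D6 replicate 1. Of 9 neural crest genes 6 rose (Sox9 1.23 ± 0.14, Snai2 0.86 ± 0.12), and the counts for this list changed when single libraries were left out. The 5 lists had adjusted p = 2.86e-07, 0.00364, 0.00369, 3.94e-04 and 0.00987, and adjusted p = 0.102, 0.103, 0.263, 0.102 and 0.139 with an estimated correlation.

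Of 12 Wnt targets 6 fell (Nkd1 -0.38 ± 0.06, Lef1 -0.34 ± 0.06), with a median of -0.19, or -0.30 without D7 replicate 1. Its test gave adjusted p = 0.0116, adjusted p = 0.263 with an estimated correlation, and 0.0515 without D7 replicate 2. Of 10 Fgf-Erk targets 7 fell (Il17rd -0.77 ± 0.05, Etv4 -0.61 ± 0.05), and the list had adjusted p = 6.00e-05, adjusted p = 0.212 with an estimated correlation. Of 14 Tgf-β targets 6 rose and 1 fell (Tgfbi 1.43 ± 0.07, Ctgf 0.98 ± 0.07). These counts were 3 and 0 without D7 replicate 2, 6 and 0 without D7 replicate 1, 7 and 0 without D6 replicate 2 and 8 and 0 without either D2 library. Its adjusted p was 0.0247, but 0.133 without D6 replicate 1, and adjusted p = 0.212 with an estimated correlation. Of 9 retinoic acid response genes 7 rose (Rarb 1.09 ± 0.09, Crabp1 0.63 ± 0.06) and 1 fell (Stra6 -0.36 ± 0.05). The list had adjusted p = 0.0114, adjusted p = 0.139 with an estimated correlation. In the Lin28 and let-7 list 6 fell (Lin28a -0.78 ± 0.04, Arid3b -0.81 ± 0.04) and Mycn rose (0.57 ± 0.04). For this list camera gave adjusted p = 0.0103, adjusted p = 0.333 with an estimated correlation, and 0.0517 without D6 replicate 1.

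Of 11 embryo-fibroblast genes 8 rose (Col1a1 1.74 ± 0.11, Col1a2 1.61 ± 0.12), as did 8 of 9 immediate early genes (Jun 1.73 ± 0.08, Egr1 1.48 ± 0.09). So did 8 of 10 hypoxia and glycolysis genes (Adm 1.30 ± 0.22, Bnip3 1.07 ± 0.07) and 8 of 10 cholesterol synthesis genes (Dhcr7 0.41 ± 0.04), while 9 of 10 DNA replication genes fell (Mcm5 -0.30 ± 0.03). The 5 lists had adjusted p = 9.01e-04, 9.04e-04, 5.36e-05, 7.27e-04 and 2.60e-04, and adjusted p = 0.186, 0.265, 0.102, 0.103 and 0.149 with an estimated correlation. The Hox lists had adjusted p = 0.156, 0.741 and 0.79, and that of groups 1 to 4 had 0.0410 without D6 replicate 2. Hoxd3 rose by 0.65 ± 0.11 and Hoxa7 fell (-0.38 ± 0.06), while Hoxb9 (0.12 ± 0.06) and Hoxc10 (0.05 ± 0.06) did not pass. The remaining lists had no call: naive pluripotency (adjusted p = 0.363, 0.0141 without D6 replicate 2), primed epiblast (0.934), forebrain (0.264), endoderm (0.37), node (0.92), and lateral plate (0.956). Nor had the Bmp targets (adjusted p = 0.104, 0.0444 without either D2 library), epithelial (0.0801, 0.0151 without D6 replicate 2 and 0.0489 without either D7G library) and mesenchymal (0.433) lists. The same held for mitosis (adjusted p = 0.211) and the p53 targets (0.0747, 0.0438 without D6 replicate 2 and 0.0467 with library totals). The Bmp and epithelial lists had adjusted p = 0.0317 and 0.0241 without a filter, and 0.0319 and 0.0397 with only the libraries of both groups.

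Of all genes 3853 were higher and 2929 lower on D7, 494 and 133 of them by at least 2-fold, and without D7 replicate 2 the higher count was 2323. Camera called 15 lists, 9 up and 6 down, and with an estimated correlation 0 passed, 8 at unadjusted p under 0.05, while fry passed 17 by direction and 26 mixed. The Hox 5 to 9, primed epiblast and node lists differed in sign between median, mean and test. Member counts over a list alone differed for Hox 1 to 4 (3 higher, 6 lower), Hox 10 to 13 (0 and 0), presomitic (2 and 11), forebrain (0 and 0), Fgf-Erk (0 and 8), Tgf-β (8 and 1) and epithelial genes (7 and 0).

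**Figure D2:**
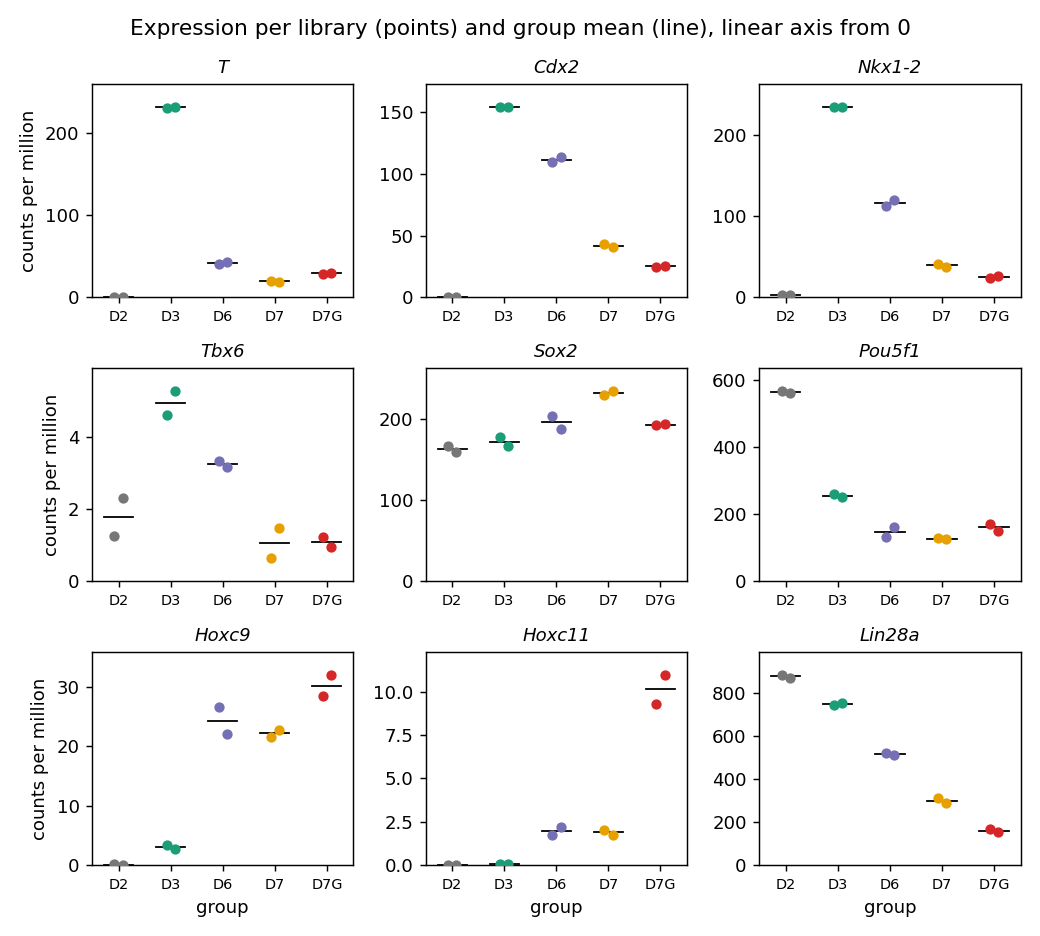
CPM of each library and the group mean for 9 genes of the posterior axis, the mesoderm, the neural lineage and pluripotency, from D2 to D7 and D7G.

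The comparison of D7G with D7 asked what changed with 24 h of Gdf11. All 12 Hox genes of paralogue groups 10 to 13, which pattern the lumbar to caudal axis, rose. Hoxc11 went from 1.91 ± 0.183 to 10.1 ± 1.18 CPM (2.41 ± 0.15, adjusted p = 2.91e-10). Hoxd12 rose from 2.24 ± 0.139 to 11 ± 0.418 (2.30 ± 0.15) and Hoxa10 from 22.2 ± 0.651 to 45.1 ± 0.133 (1.02 ± 0.07). In groups 1 to 4, which pattern hindbrain and neck, 5 fell and 7 did not pass, and Hoxc4 fell from 78.1 ± 1.34 to 59.6 ± 5.08 CPM (-0.39 ± 0.05). All 14 targets of Tgf-β, Activin and Nodal signalling rose, among them the inhibitors Pmepa1 (2.24 ± 0.07) and Smad7 (1.33 ± 0.07). Cdx2 fell from 41.9 ± 1.68 to 25 ± 0.427 CPM (-0.75 ± 0.05). Lin28a, a let-7 inhibitor of early embryonic cells, also fell (-0.90 ± 0.04), while T rose from 19.8 ± 0.676 to 29.3 ± 0.269 (0.56 ± 0.06). Sox2 fell to 193 ± 0.564 CPM (-0.27 ± 0.04), Sox1 to 39 ± 0.256 (-0.68 ± 0.06) and Gdf11 to 42.9 ± 2.02 (-0.28 ± 0.06). Pou5f1 rose to 161 ± 15.8 (0.33 ± 0.07), and Tbx6 stood at 1.09 ± 0.183 (0.04 ± 0.34, adjusted p = 0.947).

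The largest rises were Inhba, which encodes the Activin A subunit (0.12 ± 0.043 to 5.97 ± 1.71 CPM, 5.59 ± 0.36), the matrix metalloprotease gene Mmp9 (1.22 ± 0.239 to 39 ± 12.3, 5.00 ± 0.22) and Brinp1 (4.83 ± 0.35). Next came Adamtsl2 (4.34 ± 0.20), the small GTPase gene Rhoj (4.25 ± 0.27, or 5.00 without D7 replicate 1) and Ldlrad4, an inhibitor of Tgf-β signalling (4.13 ± 0.22). Cd40 (4.06 ± 0.13), the matrix glycoprotein gene Tnc (7.18 ± 0.753 to 113 ± 24.7, 3.98 ± 0.13) and Lin7a (3.92 ± 0.19) also rose. The largest falls were Hes3, a Notch-pathway repressor of neural progenitors (-2.67 ± 0.14), Meox1 (-2.42 ± 0.15), Sema3d (-2.36 ± 0.14) and the receptor gene Ret (-2.09 ± 0.08). The sodium channel gene Scn4b (-2.09 ± 0.12), Crabp2, which binds retinoic acid (458 ± 12.9 to 124 ± 0.198 CPM, -1.89 ± 0.05), Foxc2 (-1.86 ± 0.21) and Arg1 (-1.82 ± 0.12) fell too. Hoxaas3, an antisense transcript across the central Hoxa cluster, fell (-2.16 ± 0.07, or -1.31 in the second table).

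Of the remaining genes in groups 10 to 13, Hoxa13 rose by 2.23 ± 0.25, Hoxd11 by 2.06 ± 0.12, and Hoxa11 by 1.69 ± 0.12. Hoxd13 rose by 1.64 ± 0.12, Hoxd10 by 1.61 ± 0.11, Hoxc13 by 0.87 ± 0.17 and Hoxc10, the most abundant at 85.8 ± 5.54 CPM, by 0.87 ± 0.06. Hoxc12 rose by 2.39 ± 0.42, or 3.91 without D7 replicate 1 and 1.64 without D7 replicate 2. Hoxb13 rose by 0.90 ± 0.24 (adjusted p = 0.00567, but 0.0691 without D7 replicate 2 and 0.0965 by DESeq2). In groups 5 to 9, 10 rose, 2 fell and 3 did not pass, with 7 rises and 1 fall without D7 replicate 1, 10 and 1 without D7G replicate 1 and 6 and 2 without D7G replicate 2. Hoxd9 (0.82 ± 0.08), Hoxa5 (0.65 ± 0.07), Hoxc6 (0.49 ± 0.07), Hoxc5 (0.48 ± 0.08), Hoxc8 (0.47 ± 0.07) and Hoxc9 (0.45 ± 0.10) rose. Hoxb9, the most abundant Hox gene, fell from 209 ± 14.2 to 147 ± 15.9 CPM (-0.50 ± 0.06). Calls that single libraries ended were those of Hoxa6 (0.44 ± 0.13, adjusted p = 0.110 without D7 replicate 1) and Hoxa7 (0.23 ± 0.06, 0.0991 without D7G replicate 2). The same held for Hoxb5 (0.35 ± 0.13, adjusted p = 0.515 without D7G replicate 2), Hoxb6 (0.19 ± 0.07, 0.399 without D7G replicate 2) and Hoxb8 (-0.19 ± 0.07, 0.196 without D7G replicate 1). Hoxb7 (-0.19 ± 0.08, adjusted p = 0.0811; -0.53 with adjusted p = 2.21e-06 in the second table), Hoxd8 (0.10 ± 0.06) and Hoxa9 (0.02 ± 0.05) did not pass.

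In groups 1 to 4 Hoxb4 (-0.30 ± 0.07) and Hoxb3 (-0.24 ± 0.06) were also among the falls. Hoxd4 (-0.15 ± 0.11), Hoxd3 (-0.09 ± 0.11), Hoxa4 (0.08 ± 0.11), Hoxa3 (-0.08 ± 0.07), Hoxa2 (0.06 ± 0.09) and Hoxb2 (-0.01 ± 0.07) were among those that did not pass. The median of this list was -0.16, or -0.28 without D7G replicate 2. Its adjusted p was 0.0438, adjusted p = 0.452 with an estimated correlation, and 0.0657 with a filter of at least 1 CPM. It was 0.0510, 0.0511, 0.0988 and 0.209 without D3 replicate 1, D3 replicate 2, D7 replicate 2 and D7G replicate 1. Groups 5 to 9 had a median of 0.35 (adjusted p = 0.262, 0.0386 without either D2 library) and groups 10 to 13 one of 1.66 (adjusted p = 2.43e-05, adjusted p = 0.0968 with an estimated correlation).

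**Figure D3:**
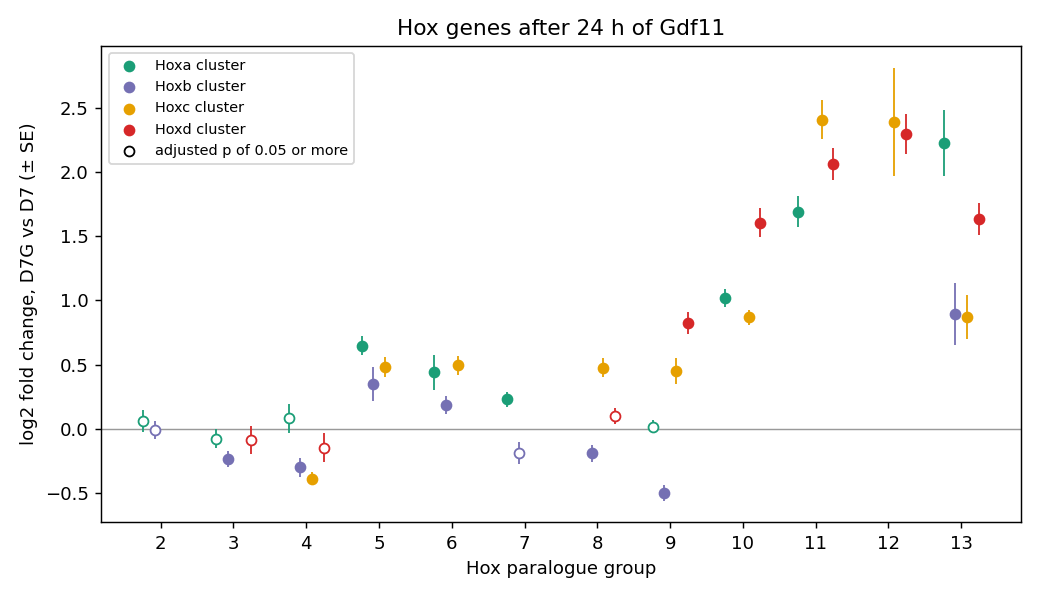
Log2 fold change of Hox genes of paralogue groups 2 to 13 with Gdf11 (D7G against D7, ± SE) by group and cluster, with open symbols for genes that did not pass.

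In the NMP list 7 rose, such as Evx1 (1.91 ± 0.11) and Wnt5a (1.13 ± 0.08), with 4 rises without D7 replicate 2 or D7G replicate 2. In the same list 5 fell, such as Cdx4 (-1.51 ± 0.06), Sp8 (-0.97 ± 0.09), Fgf8 (-0.89 ± 0.12) and Nkx1-2 (-0.68 ± 0.06), and the list had adjusted p = 0.66. In the presomitic and somitic list 4 rose (Rspo3 1.17 ± 0.13) and 5 fell (Hes7 -1.78 ± 0.42), with adjusted p = 0.495. Of 14 spinal cord genes 7 fell, such as Irx3 (-1.10 ± 0.06), Hes5 (-0.91 ± 0.08), Pax7 (-0.81 ± 0.08) and Pax6 (-0.56 ± 0.09), and 3 rose. The list had adjusted p = 0.0094, adjusted p = 0.307 with an estimated correlation. Of this list 1 rose and 7 fell without either D3 library, 0 and 8 without D7 replicate 1, 0 and 5 without D7 replicate 2, 0 and 7 without D7G replicate 1, and 1 and 6 without D7G replicate 2. Of 12 neuron genes 8 rose, such as the LIM homeobox genes Lhx5 (2 ± 0.0725 to 9.83 ± 1.27 CPM, 2.30 ± 0.16) and Lhx1 (1.44 ± 0.28), Nhlh2 (1.86 ± 0.12) and Tubb3, a neuronal tubulin (1.13 ± 0.05). Nhlh1 (-0.11 ± 0.14) did not pass. Of 9 neural crest genes 7 rose, or 4 without either D7 library, such as Ets1 (1.62 ± 0.08) and Tfap2b (1.29 ± 0.15). The neuron and neural crest lists had adjusted p = 3.13e-04 and 0.00508, and adjusted p = 0.0968 for each with an estimated correlation.

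Of 9 endoderm genes 6 rose (Cldn6 0.66 ± 0.07, Sox17 0.58 ± 0.10, and Afp 2.88 ± 0.37, or 2.03 without D7G replicate 1). The median was 0.49, or 0.27 with adjusted p = 0.0577 without D7G replicate 1. Of 5 node and notochord genes 4 rose (Nog 1.11 ± 0.12, and Foxa2, also in the endoderm list, 0.71 ± 0.11). These lists had adjusted p = 0.0186 and 0.015, and adjusted p = 0.451 and 0.148 with an estimated correlation. All 12 naive pluripotency genes rose by small amounts (Tbx3 0.55 ± 0.07, Nr0b1 0.45 ± 0.09, Esrrb 0.36 ± 0.06, Klf4 0.34 ± 0.06), or 7 without D7 replicate 2 or D7G replicate 1. Of 12 primed epiblast genes 8 rose (Utf1 0.56 ± 0.07, Dnmt3a 0.52 ± 0.04, Tdgf1 0.48 ± 0.07) and 2 fell. These counts were 6 and 1 without D7 replicate 1 or D7G replicate 1. The naive and primed lists had adjusted p = 0.00165 and 0.0328 (primed 0.0577 without D7G replicate 1), and adjusted p = 0.434 and 0.165 with an estimated correlation. All 10 epithelial genes rose (Krt8 1.03 ± 0.10, Cdh1 0.62 ± 0.07). Of the mesenchymal genes, 6 of 9 rose (Cdh11 1.87 ± 0.08, Snai1 1.25 ± 0.12, Twist1 1.06 ± 0.07) and 1 fell (Cdh2 -0.36 ± 0.05), or 2 fell without any library of D2, D3 or D6, D7 replicate 2 or D7G replicate 2. Their adjusted p values were 1.69e-04 and 0.0379 (mesenchymal 0.0630 without D7G replicate 2 and 0.0537 with only the libraries of both groups), and adjusted p = 0.35 and 0.416 with an estimated correlation.

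Of 11 embryo-fibroblast genes 9 rose, such as the collagen genes Col1a1 (27.3 ± 1.93 to 242 ± 14.4 CPM, 3.14 ± 0.08) and Col1a2 (2.40 ± 0.08), Twist2 (2.30 ± 0.13) and Prrx1 (2.08 ± 0.07). Fap fell (-0.48 ± 0.13) and Dcn (0.35 ± 0.41) did not pass. Camera gave adjusted p = 9.20e-06, adjusted p = 0.0968 with an estimated correlation. In the Tgf-β, Activin and Nodal list (median 0.98, adjusted p = 2.28e-09, adjusted p = 0.0612 with an estimated correlation) Skil (1.19 ± 0.04) and Lefty1 (1.05 ± 0.08) also rose. Of 12 Wnt targets 9 rose (Apcdd1 2.33 ± 0.08, Dkk1 1.35 ± 0.13, Axin2 0.47 ± 0.06) and 2 fell (Ccnd1 -0.36 ± 0.04). Of 10 Fgf-Erk targets 7 rose (Il17rd 1.06 ± 0.05, Dusp6 0.60 ± 0.05) and 1 fell (Dusp4 -0.28 ± 0.05). Of 8 Bmp targets 6 rose (Msx2 1.46 ± 0.11, Id4 0.87 ± 0.11) and 2 fell (Id3 -0.29 ± 0.07). These 3 lists had adjusted p = 0.0169, 0.00579 and 0.0334 (Bmp 0.0572 without either D2 library and 0.0682 without D7G replicate 2), and adjusted p = 0.3, 0.365 and 0.246 with an estimated correlation.

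In the Lin28 and let-7 list 9 of 10 fell (Lin28b -0.83 ± 0.04, Arid3a -0.64 ± 0.05), while Hmga2, a let-7 target, rose (0.54 ± 0.05). All 10 mitosis genes fell (Aurkb -0.43 ± 0.05, Plk1 -0.27 ± 0.04), as did all 10 DNA replication genes (Gins2 -0.46 ± 0.05, Mcm7 -0.35 ± 0.03). Of 10 hypoxia and glycolysis genes 7 fell (the glucose transporter gene Slc2a1 -1.20 ± 0.05, Pgk1 -0.75 ± 0.08, Ldha -0.74 ± 0.04), with 1 rise without D7G replicate 2. The 4 lists had adjusted p = 1.09e-04, 4.28e-05, 7.66e-06 and 2.25e-04, and adjusted p = 0.205, 0.165, 0.0968 and 0.0968 with an estimated correlation.

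Of all genes 4241 were higher and 3420 lower in D7G, 799 and 180 of them by at least 2-fold. Camera called 20 lists, 14 up and 6 down, and with an estimated correlation 0 passed, 8 at unadjusted p under 0.05, while fry passed 24 by direction and 29 mixed. The NMP and p53 lists differed in sign between median, mean and test. Member counts over a list alone differed for Hox 5 to 9 (10 higher, 3 lower), presomitic (4 and 6), spinal cord (3 and 8), mesenchymal (6 and 2), immediate early (4 and 4) and p53 genes (5 and 4). Gm42418, which overlaps ribosomal RNA sequence, took 0.374 to 0.456% of counts in D2, 0.313 to 0.334% in D3, 0.203 to 0.258% in D6, 0.263 to 0.318% in D7 and 0.154 to 0.162% in D7G. Ribosomal protein genes took 2.28 to 2.31%, 2.42 to 2.47%, 2.15 to 2.18%, 2.23 to 2.26% and 1.98 to 1.99%. Mitochondrial genes took 1.86 to 1.90%, 2.01 to 2.07%, 2.38 to 2.40%, 2.25% and 2.38 to 2.48%. These shares, possible signs of library quality, thus differed without overlap in each of the 4 comparisons. The labels name no vehicle control for Gdf11.

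**Figure D4:**
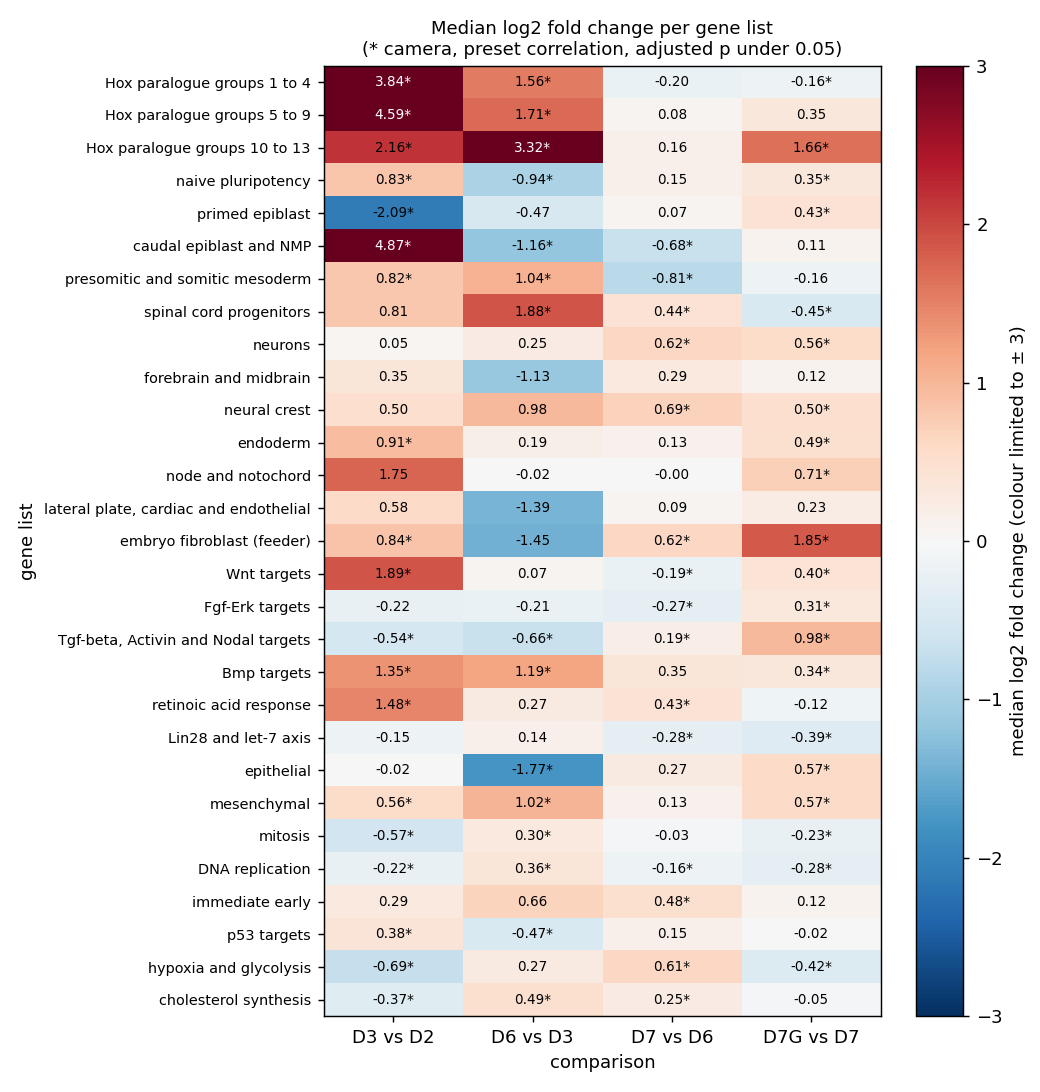
Median log2 fold change of the 29 gene lists in the 4 comparisons, with asterisks where camera passed at its preset correlation.

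The effect of Gdf11 on the 39 tested Hox genes rose with paralogue group, though unevenly. It ran from -0.39 (Hoxc4) to 0.08 (Hoxa4) in group 4, from -0.50 (Hoxb9) to 0.82 (Hoxd9) in group 9, from 1.69 (Hoxa11) to 2.41 (Hoxc11) in group 11 and from 0.87 (Hoxc13) to 2.23 (Hoxa13) in group 13. The Spearman coefficient was 0.795 and the Pearson coefficient 0.781, each with a two-sided permutation p = 1e-05, the smallest possible with 100000 shuffles (adjusted over the 2 planned relations 2e-05, over all 4 4e-05). From D3 to D6 the same relation was weaker (Spearman 0.318, p = 0.0493, adjusted over the 2 planned relations also 0.0493 and over 4 0.0657; Pearson 0.308, permutation p = 0.0577, over 4 0.0769). The Spearman p exceeded 0.05 without D3 replicate 1 (0.0501), D3 replicate 2 (0.0546) or D6 replicate 2 (0.0783). Hoxc12, with 0 counts on D3, ranked first here by its fitted value. With it at its bound, an alternative added after the data were seen, the coefficient was 0.298 (permutation p = 0.0658), and without it 0.288 (permutation p = 0.0794), so this relation did not pass in either. Among the 39 genes, in a pair of relations added after the data were seen, the Spearman coefficient was 0.380 from D6 to D7 (permutation p = 0.0184, adjusted 0.0367) and -0.283 from D2 to D3 (permutation p = 0.0818). The latter used fitted values for Hoxd3 and Hoxc11, with 0 counts on D2, and for Hoxc12, with 0 counts on both days. With Hoxc12 left out and the others at their bounds it was -0.266 (permutation p = 0.107). Hox genes of a cluster share regulation and are not independent replicates, so these p values describe the ranking of genes and not a repeat of the experiment.

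The last question was how far genes that changed with Gdf11 also changed from D3 to D6, a pair of comparisons without a shared library. Of 5793 genes called in both, 1842 went the same way and 3951 opposite ways. Col1a1 (-3.58 from D3 to D6, 3.14 with Gdf11), Gadd45b (-2.70 and 0.99), Krt8 (-1.78 and 1.03) and Nodal (-1.19 and 0.59) fell and then rose. Meox1 (7.26 and -2.42), Irx3 (3.07 and -1.10) and Crabp2 (1.96 and -1.89) rose and then fell. Hoxc10 (5.71 and 0.87), Hoxd11 (3.92 and 2.06), Prrx1 (2.33 and 2.08) and Twist1 (2.86 and 1.06) rose in both. Cdx4 (-0.47 and -1.51) and Lin28a (-0.53 and -0.90) fell in both. Both calls were up for 1227 genes (1375.7 if the lists were independent) and down for 615 (1138.2). They were up with Gdf11 after a fall for 2040 (1411.5) and down after a rise for 1911 (1109.3). At 2-fold or more in both, 142 genes went the same way, 131 up (55.5 if independent) and 11 down (25.5), and 320 opposite ways. Of these, 239 (113.0) were up with Gdf11 after a fall and 81 (12.5) down after a rise, so with this minimum shared rises, too, exceeded the count for independent lists. Across all tested genes the fold changes correlated at -0.169 (Spearman -0.209), and as genes are not independent no p was computed. Of the genes named as moving opposite ways, some had already turned from D6 to D7 without Gdf11. In that step Col1a1 (1.74) and Gadd45b (0.93) rose and Meox1 (-1.66) fell. Krt8 (0.10) and Nodal (-0.04) did not pass there, while Irx3 (0.24) and Crabp2 (0.45) still rose.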

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

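The counts of at least 2-fold combined with another choice, the adjustment over 4 Hox relations, the treatment of Hox genes with 0 counts and the member counts without a library were chosen only after the result was seen. Among the genes named by rule or in a list, the lists and the relations, no call turned direction under any alternative, and other called genes were not compared one by one. An outcome counted as unchanged also where a gene or list had no call in either fit, so unchanged outcomes are not counts of calls that held. For the genes named by rule or in a list 27600 outcomes were unchanged, 230 became stronger and 795 weaker. For the lists 2092 were unchanged, 23 became stronger and 89 weaker, 67 of these with the correlation estimated in camera. With that estimate 2, 0, 0 and 0 lists kept their calls in D3 against D2, D6 against D3, D7 against D6 and D7G against D7. A minimum of 2-fold left 1632 genes higher and 1036 lower in D3 against D2, 1308 and 2662 in D6 against D3, 494 and 133 in D7 against D6 and 799 and 180 in D7G against D7, and in both D7G against D7 and D6 against D3 142 genes changing the same way and 320 opposite ways. From D6 to D7, DESeq2 with the 2-fold minimum gave 304 higher and 73 lower and a filter of at least 1 CPM gave 86 lower. Leaving out each library in turn gave 4748 to 5779 genes higher in D3 against D2, 5415 to 6208 in D6 against D3, 2323 (without D7 replicate 2) to 3680 in D7 against D6 and 3058 to 4304 in D7G against D7. The number of lists called was 19 to 19, 15 to 16, 13 to 19 and 17 to 20. The Spearman coefficient of Gdf11 fold change with Hox paralogue group stayed at 0.773 to 0.816, while that from D3 to D6 (0.318, p = 0.0493) ranged from 0.285 to 0.346. Its p was 0.0658 with Hoxc12, which has 0 counts on D3, at its bound (0.298) and 0.0794 without it (0.288). It was also 0.0657 adjusted over 4 relations, 0.0501 without D3 replicate 1 (0.317), 0.0546 without D3 replicate 2 (0.311), 0.0783 without D6 replicate 2 (0.285), 0.0555 with limma-voom (0.310), 0.0592 in the second table (0.308) and 0.0795 with only the libraries of both groups (0.288). With scaling by library totals the share of calls that were higher was 60.5, 41.6, 66.1 and 55.2% in the 4 comparisons. A term for the replicate number, a replicate block, gave 5606 and 5485, 6149 and 6308, 3932 and 3036, and 4304 and 3503 genes higher and lower, and ended the call of the presomitic list from D3 to D6 (adjusted p = 0.0552). Replicates of the same number were no closer across groups, with residual correlations of -0.042 to 0.049 and 0 of 10 pairs over 0.1. The cause was not tested for any of the changed results. Depth limits the genes under about 1 CPM, such as Hoxc12 and Hoxa13 before Gdf11, more than the counts above.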

Other observations

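In this part the scaling test of the naive pluripotency list, the bootstrap intervals and the counts of shared list genes were chosen only after the result was seen. Gdf11 split the retinoic acid response list, in which Crabp2 (-1.89 ± 0.05), Crabp1 (-0.44 ± 0.06) and Rarb, a receptor gene (-0.42 ± 0.08), were among 4 falls. Cyp26b1 (1.39 ± 0.23) and Cyp26a1 (0.55 ± 0.09), which degrade retinoic acid, were among 4 rises, and the list had adjusted p = 0.653. The p53 targets also split, with Pmaip1 (0.83 ± 0.05) and Cdkn1a (0.57 ± 0.04) among 4 rises and Bbc3 (-0.48 ± 0.06) among 4 falls, and the list had adjusted p = 0.837. Of the immediate early genes 4 rose (Junb 0.69 ± 0.08) and 2 fell (Egr1 -0.41 ± 0.08), and the list had adjusted p = 0.495. These counts were 4 and 1 without D7 replicate 2, 2 and 4 without D7G replicate 1 and 5 and 1 without D7G replicate 2. Of the cholesterol synthesis genes 2 rose (Insig1 0.40 ± 0.03), or 1 without either D3, either D7G or D7 replicate 2. In this list 3 fell (Dhcr7 -0.26 ± 0.04), or 4 without D7G replicate 2, and the list had adjusted p = 0.495.

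In the lateral plate list 3 rose, foremost Bmp4, a ligand of ventral and posterior mesoderm (17.8 ± 1 to 59 ± 8.33 CPM, 1.73 ± 0.08), and the list had adjusted p = 0.334. There were 2 rises and 1 fall without D7 replicate 2, 1 rise without D7G replicate 1 and 3 rises and 1 fall without D7G replicate 2. In the forebrain and midbrain list Lhx2 rose (1.53 ± 0.26), while En1 (0.15 ± 0.10) and En2 (0.08 ± 0.07) did not pass and 1 gene fell without D7G replicate 1. The list had adjusted p = 0.495. Along the course Ldha, a glycolysis gene, fell from D2 to D3 (-0.96 ± 0.04), rose to D6 (0.76 ± 0.04) and D7 (0.32 ± 0.04) and fell with Gdf11 (-0.74 ± 0.04). Hmga2, an embryonic chromatin protein gene, rose from D2 to D3 (1.46 ± 0.06) and to D6 (2.22 ± 0.05), fell to D7 (-0.31 ± 0.05) and rose with Gdf11 (0.54 ± 0.05).

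The rise of embryo-fibroblast genes with Gdf11 (9 of 11, median 1.85) may reflect feeder cells, as the ESCs were kept on embryo fibroblasts and depleted of them once before plating, or matrix genes switched on in the cultured cells. The list's most abundant genes were Col3a1 (261 CPM in D7, 659 in D7G), Col1a1 (27.3 and 242), Prrx1 (48.9 and 206) and Acta2 (41 and 111); 9 of the 11 reached 1 CPM in D7 and 0 belonged to another list. In a second list of 24 fibroblast genes outside the matrix, 19 tested and 10 at 1 CPM or more in D7, 7 rose, such as Anxa1 (1.64) and Pdgfrb (1.13), and the median was 0.44. That value lay under the 0.5 set beforehand for ruling feeders out. The bootstrap interval added once it was seen (-0.04 to 0.70, 10000 resamples) spans 0.5, so this list does not tell feeder RNA apart from a change in the cells. The first list had also risen from D6 to D7 without Gdf11 (8 of 11 higher, 0 lower, median 0.62). With Gdf11 its member Fap fell. Of 16 other matrix genes, which many cell types make, 15 rose (median 0.82), among them Bgn (3.80), Thbs1 (2.58) and the basement membrane gene Col4a1 (0.36, 1797 to 2298 CPM). This met the rise set beforehand for a matrix response in the cells (median above 0.5 and at least 75% higher). Feeder cells can be among those cell types, so the list does not tell such a response from feeder RNA, and a feeder share stays open.

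The small shared rise of naive pluripotency genes with Gdf11 (12 of 12, or 7 without D7 replicate 2 or D7G replicate 1, median 0.35, range 0.30 to 0.55) might come from scaling, from a larger share of little-differentiated stem cells, or from regulation within cells. Under 3 other scalings the lowest median was 0.33. These scalings shifted D7G against D7 by only -0.008, -0.018 and 0.0002, so the rise did not hinge on the choice among them. They could not test an error that all scalings share. In a second list of 19 ESC genes 13 rose (68.4%, under the 75% set beforehand) with a median of 0.39, among them Tdh, L1td1 and Zfp57, while Mybl2 (0.02) did not pass. Regulation and cell share stay open, because the rise in the second list was of the same size but did not reach enough of its genes. The naive genes also moved together between replicate libraries, with an estimated correlation of 0.73, so their 12 rises are not independent. Their fold changes had an SD of 0.085 over genes and a median SE of 0.085. As correlated genes share part of that error, these values do not show whether all rose equally.

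The opposite movement of genes with Gdf11 and from D3 to D6 (r = -0.169) might come from the GC content or length of genes or from noise in weakly expressed genes. After removing the trends on GC content and transcript length, known for 96.7% of genes, r was -0.176, as before the removal on the same genes. This argues against GC content and length. The design argues against noise, since in comparisons that share no library it draws r towards 0 and does not yield -0.169; among genes above the median CPM r was -0.237. Gadd45b had already risen from D6 to D7 without Gdf11 (0.93), while Krt8 (0.10) and Nodal (-0.04) did not pass in that step. Gadd45b and Nodal are also among the Tgf-β, Activin and Nodal targets, all 14 of which rose with Gdf11. Their rises therefore do not single out a return to the D3 level. Whether Gdf11 returns some genes, such as Gadd45b, Krt8 and Nodal, towards their D3 level is a hypothesis that these groups leave open, as no D6 library with Gdf11 and no earlier addition was sampled. Col1a1 and Bgn also fell and then rose (Bgn -4.28 from D3 to D6). Of 11 embryo-fibroblast genes 7 fell and 4 rose from D3 to D6 (median -1.45, camera adjusted p = 0.397), so that list was split. The feeder share left open above is open here too.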
